A study of Arabidopsis thaliana with 2 samples.

How the data were processed

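Total RNA from rosette leaves of 4-week-old wild type plants and of a homozygous T-DNA insertion mutant of ABHD11 was hybridised to a custom Agilent expression array, with 1 array per group. Per the labels' protocols, RNA was isolated with a column kit, reverse transcribed with an oligo dT primer and labelled with Cy3 during in vitro transcription. The deposited scanner files held the intensity of each spot in 1 colour, made with Agilent Feature Extraction version 11.5.1.1, per the file headers; the submitters' processing notes name the same software. Per the file headers, the processed intensity had its background subtracted and low values replaced by a surrogate, and a multiplicative trend across the array was fitted for the mutant array (root mean square 0.0995) but not for the wild type array. Per the file headers, both arrays were on 1 slide, so slide and group were not confounded. The authors also deposited a table of log2 values. Set against the scanner values, 25568 of 25569 probes with a single spot differed from the log2 processed intensity by 1 constant per array (tolerance 0.001), and the constant was near the 75th percentile, so scale and direction were settled and no centring per gene was seen. The medians of its columns were -3.20 for the wild type and -3.09 for the mutant.

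Each array held 62976 spots, of which 61657 were not controls; they made up 43613 probes, 18044 with 2 spots and 25569 with 1. Each array had 2 outlier spots, which were left out, and 0 saturated spots. Of the probes, 63.1% were well above background on the wild type array and 61.3% on the mutant array. Of the spike-in probes, 8 were well above background on both arrays, with 35 spots each, and after scaling they averaged 0.13 (SD 0.12) higher in the mutant on the log2 scale. Levels correlated between the arrays with r = 0.956 across 22985 probes, which are not independent replicates. Differences of the 2 spots of a probe correlated with r = 0.894 across 11528 probes.

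The level of a spot was log2 of the processed intensity minus the 75th percentile of the array. Spots of a probe were averaged, and a gene was the median over its probes that were well above background on both arrays. A log2 difference of 1 or more, mutant minus wild type, counted as 2-fold higher, and -1 or less as 2-fold lower. With 1 array per group no test was made and no p-value is given. A gene whose probes were all not well above background on 1 array has only a bound there: its level on the bright array minus the higher of the dim probe's own level and the lowest level among probes well above background on the dim array. No bound was given where the fold was under 1, which left 452 of 593 genes for the wild type.

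Probes were named through the RefSeq transcripts that the files list for them, matched without versions to a gene table of assembly TAIR10.1; 34626 probes matched this way and 978 through the gene name column. In all, 35152 probes were tied to 1 locus (26175 loci), 452 to several loci, which were not used, and 8009 to none. The file headers name an older build, so no coordinates are given and the table served only for names and neighbours. Whether a probe also binds transcripts of related genes was not checked here.

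The samples' groups, the alternatives, the designs, 39 gene lists of 536 members and the rule for named genes were set before the data were examined. Members whose locus carries another symbol in the table were left out: NMT2, CEK1, MCAT, KASII, FATA1, RPS5B, RPL8A, HSP22 and HSP23.6. For lists with at least 5 measured members, the median difference was placed among medians of 10000 random lists of the same size drawn from 20 bins of mean level. This percentile describes these arrays and is no test of the genotypes. Percentiles of the alternatives came from a new draw of random lists. Of 31 such lists, 9 lay above and 6 below the central 95%, and 8 lists were too small. The named genes were AT4G10030 and AT3G52570, the galactolipid synthases MGD1, MGD2, MGD3, DGD1 and DGD2, and 12 genes in each direction with the largest difference. Those 24 had to reach the median level on the brighter array, be free of saturation and have all probes at least 2-fold apart the same way. Up to 4 members of each list at least 2-fold apart, or else its 2 furthest, and up to 5 genes per direction with the largest bound were also named. Lists of pollen, tapetum, young leaf and iron-deficiency genes were added after the data had been seen.

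The alternatives were normexp background correction with an offset of 50, no multiplicative detrending, quantile, median, intensity-dependent loess (span 0.4) and spike-in scaling, no filter and a stricter filter on dim probes, the brightest probe or the mean over probes, saturated probes left out, the deposited log2 values, a weaker background call and unmatched random lists. The steps were tested on simulated data with 18036 genes and the measured probe spread: of 100 genes made with a log2 difference of 1.5, 96 were recovered, of 100 made with 3, all 100, and 44 of 17836 unchanged genes passed 2-fold. Of 200 unchanged lists of 20 genes, 10 lay outside the central 95% of random lists. The simulation used 1 spread for all levels and copied the background calls of the wild type array. It held no variation between plants or harvests and no genes that vary together. Its rates therefore check the steps and are not the error of this comparison. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.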

Results

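Gene expression was measured in rosette leaves of 4-week-old Arabidopsis thaliana plants of the Col-0 background. One sample came from the wild type and the other from a homozygous T-DNA insertion mutant labelled as a knock-out of ABHD11, an alpha/beta-fold hydrolase. Each group had 1 array, so no difference below has a replicate check, and every value describes these 2 arrays only. The arrays carried 43613 probes, of which 63.1% were well above background in the wild type and 61.3% in the mutant. The 75th percentile of the signal was 557 in the wild type and 412 in the mutant, and no spot was saturated. Replicate spots of a probe gave a spread of 0.235 (SD, 11528 probes) in the log2 difference between the arrays, and different probes of a gene gave 0.345 (SD, 4501 genes). These spreads cover spot and probe error, not variation between plants, and the number of arrays limits the precision. Levels are log2 signals relative to the 75th percentile of their array, and differences are mutant minus wild type.

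The first question was whether the targeted gene was lower in the sample labelled as mutant. The labels name ABHD11 without a locus, and AT4G10030, an alpha/beta-fold hydrolase gene, was taken as the target from knowledge of the study rather than from the files. It had a level of 0.33 in the wild type and -1.99 in the mutant, a log2 difference of -2.33 or 5.01-fold lower. Its only probe was still well above background in the mutant, with a signal of 104 against 702. The position of this probe relative to the insertion is not known here, so the value shows a lower signal at this locus and not how much intact transcript remained. The difference was -1.77 with another background correction. A related hydrolase locus, AT3G52570, was at -0.45 (SD 0.07 over 2 probes). Among the loci beside the target in the TAIR10.1 annotation, CYTC-2 (AT4G10040, cytochrome c) was at 0.90 and AT4G10000 at -0.77 (SD 0.06 over 2 probes). None of the 4 neighbours measured on both arrays was 2-fold apart, while AT4G10020 was well above background in the mutant only and at least 2.07-fold higher.

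The second question was which leaf genes differed between the genotypes. The genes furthest above the wild type in the mutant included AGP4, an arabinogalactan protein, at 5.41 (log2) and GH9B8, a glycosyl hydrolase of family 9, at 5.22. The myrosinases TGG2 and TGG1, which hydrolyse glucosinolates, were at 5.33 and 4.74 (SD 0.42 over 3 probes). The transcription factor WRKY53 was at 4.89 (SD 0.17 over 2 probes), the pectin methylesterase ATPMEPCRB at 4.76 and PCC1, a pathogen and circadian controlled gene, at 4.26 (SD 0.18 over 3 probes). The AAA ATPase BCS1 was at 4.15. AT2G30766 was at 5.02, AT3G22235 at 4.67 and the glycine-rich protein gene AT1G07135 at 4.42. The pectin methylesterase inhibitor gene AT4G02250 was 18.4-fold higher. Several of these genes were dim in the wild type, with signals of 32.7 for AGP4, 33.7 for WRKY53 and 27.7 for ATPMEPCRB. The lowest signal well above background there was 11.8, so the size of such differences is uncertain. TGG2 (375) and PCC1 (489) were brighter. Genes given here without an SD had 1 probe.

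The genes furthest below the wild type included the kinase gene CIPK25 at -4.44, the transporter gene UMAMIT33 at -3.98 and the extensin gene EXT4 at -3.64, each with 1 probe. CIPK25 had a signal of 14.8 in the mutant, near the lowest well above background there (10.6), so the size of its difference is uncertain. The peroxidase gene AT2G37130 was at -3.97, with a spread of 0.86 (SD) between its 2 probes. ASN1, the dark-induced asparagine synthetase, was at -3.02 (SD 0.20 over 3 probes). The transcription factor gene MYB112 had a signal of 449 in the wild type and 41.6 in the mutant. The ATPase gene DAA1 was at -2.86 (SD 0.02 over 2 probes), the latex-protein-like gene AT4G23680 at -2.89 (SD 0.38 over 2 probes) and the small peptide gene RTFL21 at -2.77. AT5G10625 was at -3.04 and AT1G77145 at -3.02. The glycine-rich protein gene AT2G05540, with a signal of 63161 in the wild type and 7531 in the mutant, was at -2.63 (SD 0.02 over 2 probes).

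**Figure D1:**
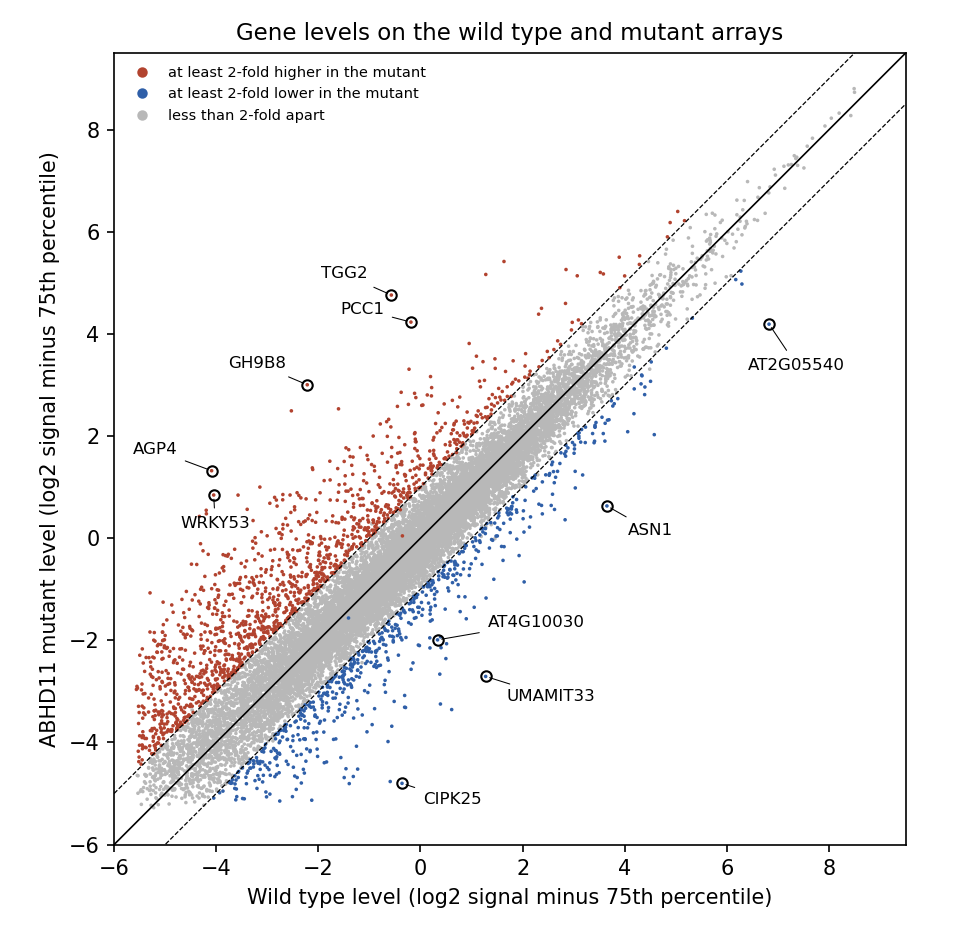
Level of each of 17295 genes in the wild type (horizontal axis) and the ABHD11 mutant (vertical axis), as log2 signal minus the 75th percentile of the array; each point is 1 gene on 1 array per group, the solid line marks equal levels and the dashed lines mark 2-fold, and colour follows the median over probes. The 1351 red genes lie above the upper dashed line more often at low levels, and TGG2 at 5.33, CIPK25 at -4.44 and the target AT4G10030 at -2.33 are among the labelled genes.

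In total, 17295 genes were well above background on both arrays, and 1351 of them (7.81%) were at least 2-fold higher and 613 (3.54%) at least 2-fold lower in the mutant. At least 4-fold differences were seen for 398 genes above and 73 below the wild type, and at least 8-fold for 104 and 16. Higher genes made up 68.8% of the 2-fold set, and 57.1% of it (1110 higher, 835 lower) when the arrays were scaled on spike-in probes, which moved the median of all genes by -0.13. When genes were divided by mean level into 4 groups of equal size, the dimmest group held 672 higher and 249 lower genes and the brightest 151 and 108. Of 343 genes with several probes and a 2-fold difference, 98.0% had all probes on the same side of 0 and 61.2% had all probes at least 2-fold apart. The counts depended on the processing: another background correction gave 819 higher and 242 lower genes, a stricter filter on dim probes 385 and 213, and no filter 3062 and 1375.

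The comparison also asked whether genes of lipid metabolism differed, since the targeted protein belongs to a hydrolase family. Most lipid genes were less than 2-fold apart: of 105 measured members of 7 lipid lists, 4 were higher, 4 were lower and 97 (92.4%) were in between. Over all 17295 genes, 7.81% were higher and 3.54% lower, so most genes of any kind were also in between. For the galactolipid synthases, MGD1 was at 0.44, MGD2 at 0.52, DGD1 at -0.26 (SD 0.01 over 2 probes) and DGD2 at 0.13 (SD 0.10 over 2 probes). MGD3 was not well above background on either array. None of the 8 measured galactolipid and sulfolipid genes reached 2-fold, and their median was 0.05 (-0.07 with spike-in scaling).

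Fatty acid desaturases stood highest among the lipid lists, with a median of 0.42 over 8 genes, above 99.1% of 10000 random lists of the same size matched on mean expression. FAD3, the omega-3 desaturase of the endoplasmic reticulum, was at 2.35 (SD 0.19 over 4 probes) and the plastid omega-3 desaturase FAD8 at 1.70, while ADS2 was at -1.31. The percentile was 97.4 against random lists that were not matched and 95.1 with the stricter filter on dim probes, both inside the central range. Phospholipid synthesis genes had a median of -0.31 over 20 genes, at the 0.63 percentile, with PSD2, a phosphatidylserine decarboxylase, at -1.08. With normexp correction the median was -0.13 (percentile 5.45) and with no filter the percentile was 3.10, both inside the central range. The phosphoethanolamine methyltransferase gene NMT3 (AT1G73600) went the other way, at 2.31. None of 19 phospholipases and other lipid hydrolases reached 2-fold in the main values (median 0.05, and -0.07 with spike-in scaling), while 1 was lower with quantile, loess or spike-in scaling and 3 of 24 were higher with no filter. The furthest apart were PLDP2 at -0.99 and PLDGAMMA1 at 0.83. Of 20 plastid fatty acid synthesis genes, PDH-E1 ALPHA alone reached 2-fold, at -1.27 (SD 0.71 over 3 probes). The list median was -0.01, changing sign with normexp correction (0.06), with intensity-dependent loess (0.01) and with the stricter filter (0.0038). Glycerolipid assembly genes had a median of -0.13 over 18 genes, with LPAT4 at 1.02 (SD 0.16 over 2 probes) and LPLAT2 at -1.06. Peroxisomal beta-oxidation genes had a median of -0.14 over 12 genes, none 2-fold apart, with PKT3 at -0.64 (SD 0.20 over 5 probes) and KAT5 at 0.63 (SD 0.57 over 2 probes). Of 16 wax and cutin genes, CER2 was at 1.56 and the median was 0.09 (-0.04 with spike-in scaling and -0.03 without multiplicative detrending). The median was 0.24 with normexp correction (percentile 97.55, at the limit of the central range) and 0.34 over 20 genes with no filter (percentile 96.5).

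Genes of early touch, wounding and handling responses were, among the lists fixed in advance, the one furthest above the wild type. Of 20 measured members, 19 were at least 2-fold higher and none was lower, with a median of 2.09 that lay above all 10000 matched random lists. TCH4, a touch-induced xyloglucan endotransglucosylase, was at 3.03, BAP1 at 2.80 and the transcription factor WRKY40 at 2.77 (SD 0.04 over 2 probes). Salicylate response and immunity genes were also above all 10000 random lists, with a median of 1.05 and 8 of 16 members higher. NIMIN-2 was at 2.53, WRKY70 at 1.92, SARD1 at 1.84 and EDS5, required for salicylate accumulation, at 1.78 (SD 0.04 over 2 probes). Among jasmonate synthesis genes, 4 of 10 were higher (median 0.43, percentile 98.7), with LOX4 at 1.61, LOX3 at 1.26 (SD 0.90 over 3 probes), OPCL1 at 1.21 and OPR3 at 1.09 (SD 0.10 over 2 probes). Among jasmonate response genes, 5 of 17 were higher (median 0.31, percentile 99.4), with TAT3 at 2.84, VSP2 at 1.59 (SD 0.32 over 2 probes), VSP1 at 1.21 (SD 0.60 over 4 probes) and JAZ1 at 1.15. Heat shock genes had a median of 0.30 over 11 genes, with HSFA2 at 1.36, HSP101 at 1.14 and HSA32 at -1.11. Their percentile was 97.4, near the limit of the central range, and 97.85 without multiplicative detrending. A redraw of random lists for unchanged values gave 97.6, so crossing the limit cannot be tied to the processing. The salicylate median was 0.66 with the stricter filter on dim probes.

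Lists of carbon starvation, phosphate starvation and senescence genes had medians below the wild type. Of 6 dark and sugar starvation genes, 4 were lower, and the median of -1.26 lay below all 10000 random lists. ASN1 was at -3.02, SEN1 at -2.41 (SD 0.03 over 2 probes), AT2G33830 at -1.26 (SD 0.29 over 4 probes) and DYL1 at -1.26 (SD 0.32 over 4 probes). Phosphate starvation genes had a median of -0.42 over 15 genes (percentile 0.37), with 5 lower and 1 higher. The phosphatase gene PS2 (AT1G73010) was at -3.35, PHO1;H1 at -2.55 and the acid phosphatase gene PAP17 at -1.92. PHO1, the phosphate exporter, was at 1.94. Senescence and chlorophyll breakdown genes had a median of -0.39 over 15 genes (percentile 0.32), with 4 lower and 2 higher. AT4G11910 was at -2.33, and the 2 higher genes were WRKY53 and SAG13, the latter 3.99-fold higher. The senescence list shares SEN1 with the dark and sugar starvation list and WRKY53 with the touch list, so these lists are not independent. The phosphate list had a median of 0.10 with no filter on dim probes, so its direction depended on that filter, and with the stricter filter its percentile was inside the central range. The senescence list was at percentile 2.88 without multiplicative detrending.

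Iron homeostasis genes went both ways. The transcription factor gene BHLH101 was at 2.54 and BTS, an E3 ligase of the iron response, at 1.46, whereas the ferritins FER1 and FER4 were at -2.05 (SD 0.36 over 2 probes) and -1.47 (SD 0.28 over 2 probes). The list median was 0.31 over 6 genes (percentile 92.2), 1.04 over 9 genes with no filter (percentile 99.6) and -0.12 with the stricter filter; with normexp correction the percentile was 98.6. Glucosinolate synthesis genes had a median of -0.24 over 20 genes at percentile 2.26, near the limit of the central range. The percentile was 2.75 with quantile normalization and 2.60 with the deposited values, both inside the range. A redraw of random lists for unchanged values gave 2.40, so shifts this small may come from the draw. CYP79B2 was at -1.18 (SD 0.05 over 2 probes), CYP79F1 at -1.10 (SD 0.19 over 2 probes) and SOT17 at -1.06. CYP81F2, which modifies indole glucosinolates, was at 3.01. Abscisic acid, cold and drought genes had a median of 0.03 over 16 genes (-0.10 with spike-in scaling), with KIN2 at 1.76, KIN1 at 1.66, COR15A at 1.27 and HAI1 at -1.47. Nitrate response genes had a median of 0.21 over 10 genes, with NIA1 at 1.60. Flavonoid genes had a median of -0.23 over 6 genes, with F3H at 1.94 (SD 1.58 over 2 probes), and of 0.44 over 17 genes with no filter on dim probes, so the direction depended on that filter.

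Cell cycle and DNA replication genes had a median of 1.28 over 8 measured genes (percentile 99.9), 4 of them at least 2-fold higher and none lower. The replication licensing genes MCM5, PRL (MCM7) and MCM4 were 5.77-fold, 4.94-fold and 4.59-fold higher, and the cyclin gene CYCD1;1 was at 1.85. Of the 14 members not measured on both arrays, 3 were well above background in the mutant only. Auxin response genes had a median of 0.84 over 12 genes (percentile 99.96), with IAA5 at 3.04, IAA6 at 2.58, IAA19 at 1.87 and SAUR15 at 1.39. MCM4, CYCD1;1, IAA5 and IAA6 were dim in the wild type, with signals of 18.1, 28.2, 16.9 and 33.2. The lowest signal well above background there was 11.8, so the size of such differences is uncertain. Cell wall expansion genes went both ways, with EXPA15 2.82-fold and XTH9 2.80-fold higher against EXPA11 at -1.65 and XTH24 at -1.36 (SD 0.21 over 5 probes). Their median was -0.06 over 11 genes, 0.69 with no filter on dim probes (percentile 99.75) and 0.19 with the brightest probe. With the stricter filter it was -0.24 over 7 genes (percentile 11.9). The auxin median was 0.18 (percentile 82.4) with the stricter filter, which left no cell cycle gene, and the cell cycle median was 0.69 with normexp correction.

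Markers of other cell types differed between the same 2 samples, and these differences accompany each gene group above. Xylem markers had a median of 1.41 over 7 genes (percentile 99.8), with IRX1 at 2.26, CESA4 at 1.66, IRX12 at 1.45 and XCP2 at 1.41; the median was 0.68 with normexp correction, the percentile was 95.55 with no filter, and the stricter filter left no xylem marker. Epidermis and trichome markers had a median of 0.66 over 6 genes (percentile 99.2), with MYB106 at 2.70 and TRY at 1.04; with no filter the percentile was 97.4, inside the central range, and the stricter filter left 4 genes, too few for a percentile. IRX1, IRX12, CESA4 and MYB106 had wild type signals of 16.7, 17.9, 25.1 and 16.7, near the lowest well above background there (11.8). The size of their differences is thus uncertain. Of 4 phloem markers, 3 were lower: PP2-A1 at -1.72 (SD 0.13 over 2 probes), SUC2 at -1.18 (SD 0.03 over 3 probes) and APL at -1.09 (SD 0.06 over 2 probes). The 3 measured guard cell markers had a median of 0.09 (-0.04 with spike-in scaling, and -0.29 over 5 genes with no filter), with MYB60 at -0.29 (SD 0.22 over 2 probes) and FMA at 0.27. Of 8 flower organ genes, 7 were not well above background on either array, and AGL8 was at -1.14. Of 3 measured flowering time genes, FLC, a floral repressor, was at 1.05 (SD 0.22 over 3 probes). No seed or root marker was well above background on both arrays. In a list of pollen genes chosen after other pollen genes had been seen among the highest differences, 20 of 24 measured members were at least 2-fold higher and 2 were lower, with a median of 2.83.

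Most photosynthesis, ribosome and clock genes were less than 2-fold apart. None of 40 photosystem and light-harvesting genes reached 2-fold. Their median was -0.19 (percentile 0.99), and it was 0.057 when each gene was represented by its brightest probe. LHCB2.2 was at -0.73 (SD 0.64 over 3 probes) and LHCA2 at -0.69 (SD 0.24 over 3 probes). The 5 genes of Rubisco and its activase had a median of -0.05 (0.16 with the brightest probe and 0.01 with the mean over probes), with RBCS3B at -0.26 (SD 0.27 over 4 probes) and RCA at -0.10 (SD 0.38 over 9 probes). The 9 cytosolic ribosomal protein genes had a median of -0.03, with AT3G09630 at -0.61 (SD 0.47 over 3 probes) and RP1 at -0.38 (SD 0.30 over 2 probes). Clock genes of the morning phase had a median of 0.16 over 9 genes, with LHY at 0.74 and PRR9 at -0.80. Those of the evening phase had a median of -0.15 over 6 genes, with GI at -1.05, and 2 further members were well above background in the wild type only.

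**Figure D2:**
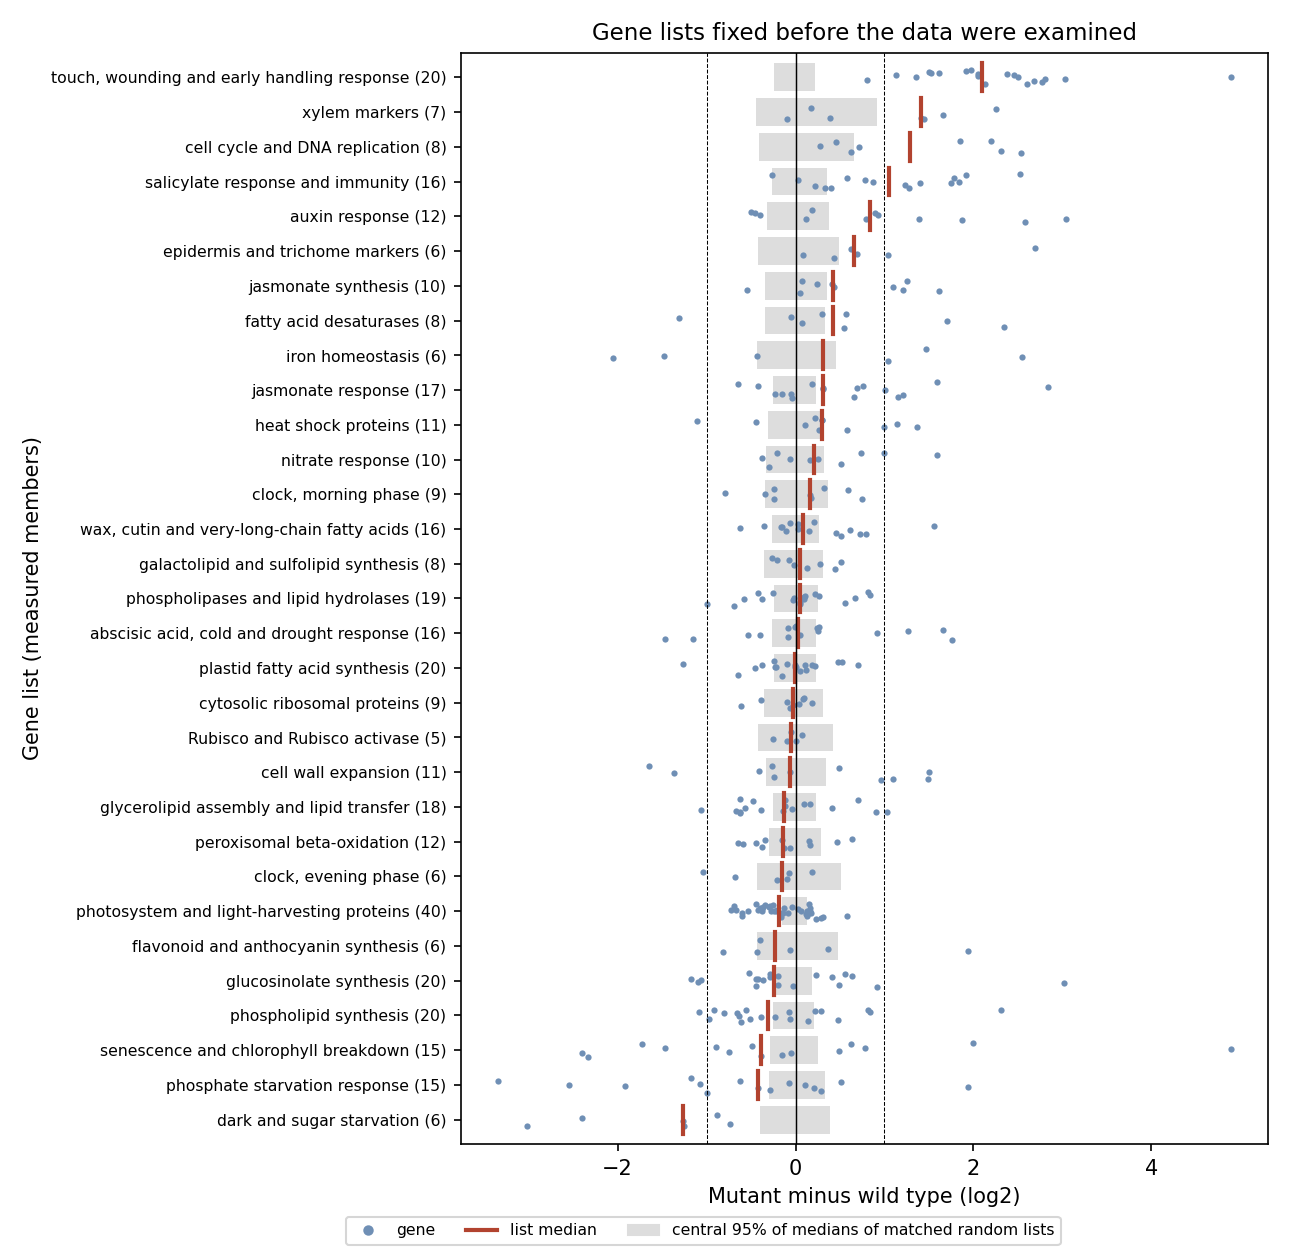
Log2 difference, mutant minus wild type, for the measured members of 31 gene lists; each point is 1 gene, the red bar is the list median, and the grey box spans the central 95% of medians of matched random lists. Medians of 9 lists lie above the grey box and those of 6 below it, from 2.09 for touch and early handling genes to -1.26 for dark and sugar starvation genes.

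A further 539 genes were well above background in the mutant only and 593 in the wild type only. Of these, 377 were at least 2-fold higher and 149 at least 2-fold lower by the bound that the background allows. The 2 counts are not on equal terms: the lowest level well above background was -5.57 in the wild type and -5.28 in the mutant. Genes seen in the wild type only were thus held to a higher floor. All 539 mutant-only genes had a bound, but only 452 of the 593 others. The largest bounds in the mutant belonged to AT5G23903 (at least 45.9-fold higher), AT1G47395 (at least 35.4-fold), the RING finger gene AT2G03000 (at least 30.1-fold), NIMIN1, an interactor of the salicylate receptor (at least 28.7-fold), and NRPE3B, an RNA polymerase subunit (at least 27.3-fold). In the other direction the largest belonged to NIT2, a nitrilase (at least 31.3-fold lower), the MATH domain gene AT3G22080 (at least 22.9-fold), AT5G03550 (at least 15.9-fold), AT5G39493 (at least 12.9-fold) and the non-coding RNA gene AT1G76892, whose level was -0.82 in the wild type. With a weaker background call, 815 genes were above background in the mutant only and 830 in the wild type only.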

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

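Probes tied to no locus in the gene table were outside every comparison, and some were well above background on 1 array only. Of 8009 such probes, 220 were well above background on the mutant array only, which is what marked them for a closer look. In the other direction, 504 were well above background on the wild type array only. Of the 2444 measured on both arrays, 190 were at least 2-fold higher and 112 at least 2-fold lower in the mutant.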

How the results depend on the processing

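The alternatives in this part were planned. No paired analysis was possible because each group had 1 array. The target gene stayed lower under all alternatives that gave it a value and was at -1.77 with normexp correction; the stricter filter removed its probe and gave no value. Normexp correction gave 819 higher and 242 lower genes, 1 lower lipid gene, and medians of 1.70 for touch genes, 0.69 for cell cycle genes and 0.68 for xylem markers; it compresses differences of dim probes by construction. With no filter on dim probes there were 3062 higher and 1375 lower genes and 9 higher lipid genes. The medians were then 0.10 for the phosphate list (reversed), 0.69 for cell wall expansion and 0.44 for flavonoid genes (both changed sign, from main values inside the central range), 0.86 for cell cycle, 1.04 for iron and 0.81 for xylem genes; this setting adds genes that are not well above background. The stricter filter, which keeps fewer genes, gave 385 higher and 213 lower genes, 1 lower lipid gene, and medians of 0.66 for salicylate, -0.12 for iron genes (a change of sign) and 0.18 for auxin genes; it left no cell cycle gene and no xylem marker, so these lists have no value there. Spike-in scaling gave 7 lower lipid genes. With the brightest probe of each gene the photosystem median was 0.057 (reversed), and with a weaker background call 815 genes were above background in the mutant only and 830 in the wild type only; the cause was not tested for either. Against unmatched random lists the desaturases were at the 97.4 percentile and the glucosinolate genes at 2.74, just inside the central range. The glucosinolate genes were also inside it with quantile normalization (2.75) and the deposited values (2.60). A redraw of random lists for unchanged values gave them 2.40, so these shifts may come from the draw. With no filter and with the stricter filter, the glucosinolate genes were at 0.50 and 0.80, outside the range. Leaving out saturated probes moved no gene value or list median, since none was saturated, while percentiles shifted slightly with the new draw of random lists. The deposited log2 values gave 1352 higher and 613 lower genes. Over the 120 named genes, 1292 of 1382 alternative values moved by less than the spread between probes, 90 moved by more and 0 reversed. Part of this count was fixed in advance. Leaving out saturated probes changed no value, and median and spike-in scaling shift all genes alike, by -0.005 and -0.13, less than that spread. For genes with 1 measured probe, the brightest probe and the mean over probes return the main value. Signal over background limits the dim genes, since the dimmest of the 4 level groups held 672 of the 1351 higher genes.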

Other observations

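The tests of pollen, of touch and early stress genes and of scaling in this part were chosen after the results were seen; the comparison of the 2 added iron lists was set before its values were seen. The genes named in this part were chosen after their values were seen.

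A list of 16 genes for DNA synthesis and leaf growth regulation was chosen after the main values were seen. Its median was 0.74 over 11 measured members (percentile 99.5). Because it was chosen after the cell cycle list was seen and also holds DNA synthesis genes, it is not independent of that list. A further 2 members were well above background in the mutant only and 1 in the wild type only. Of the 11 measured on both arrays, 5 were at least 2-fold higher and 6 were in between. The DNA polymerase alpha subunit gene POLA2 was at 3.04, HMGB6 at 2.22 (SD 0.40 over 2 probes), and the ribonucleotide reductase genes TSO2 and RNR1 were at 1.06 and 1.03. GRF3 was at -0.81, GRF1 at -0.15 and ANT at 0.11.

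Of 43 pollen genes, 24 were measured on both arrays and most of these were higher in the mutant sample, while 5 more were well above background in the mutant only and 0 in the wild type only; 17 of the 24 lay within 1 of the median of 2.83 (7.09-fold); AGP6 was at 2.80, AGP11 at 2.81, AGP23 at 2.85, BGAL11 at 3.02 and AT3G07820 and AT3G01270, with mutant levels of 1.77 and 1.73, at 3.23 and 3.14. Scaling and background correction are argued against as the whole cause, since the lowest list median among 6 such alternatives was 1.87. Flowers or buds in the sample stay open: 0 of 20 flower organ and tapetum genes were 2-fold higher, but 16 of them were not measured on both arrays (3 measured tapetum genes had a median of -0.03). The 24 measured genes were well above background in the wild type too, so their signal was not confined to the mutant sample. More RNA from pollen on the mutant leaves than on the wild type leaves may be the source. However, AT5G07420 at -1.94, CPK17 at -1.80 and SKS12 at -0.02 went against a single ratio. Fewer members thus lay near the median than the test required. Pollen, flowers and a genotype effect on these genes in leaves cannot be told apart with 1 array per group.

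Touch and early stress genes were higher in the mutant sample, with a median of 2.09. Scaling and background correction are argued against, since the lowest median among the 6 alternatives was 1.70. Harvest at another time of day stays open: the medians of the morning and evening clock lists differed by 0.31, but morning genes went both ways, 5 of 6 evening genes were below 0, GI was at -1.05, and 2 more evening genes were well above background in the wild type only. Wounding or handling of the mutant leaves before freezing may have contributed, but the jasmonate response median of 0.31 lay between the values that would favour or exclude it. Time of harvest, handling and genotype cannot be told apart, because each group is 1 sample, and the genotype itself was not tested.

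Several iron-deficiency genes were higher while ferritins were lower in the mutant sample. Besides BHLH101 and BTS, the related BHLH100 was at least 6.99-fold and the iron-response peptide gene IMA1 at least 9.62-fold higher, and AT1G47395 and AT2G30766, of the same peptide family, were among the genes furthest above the wild type. The gap between the medians of BHLH101, BTS and PYE and of FER1 and FER4 was at least 2.51 in the 6 alternatives, against 3.22 in the main values. Median and spike-in scaling shift all genes alike and cannot change this gap, so they test nothing here. Background correction, detrending, quantile and loess normalization could change it, and are argued against as the whole cause. The genes of both groups were chosen after their values were seen. An iron-deficiency state of the mutant leaves may underlie this: in the 2 added lists the median of genes that deficiency raises (0.30 over 10 genes) exceeded that of genes it lowers (-0.44 over 4 genes) by 0.73. The raised list lay at the 96.55 percentile, just inside the central 95% of random lists, and none of its members measured on both arrays reached 2-fold, so the test leaves this open, and an effect of the genotype on iron genes was not tested.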
